A study of Mus musculus with 4 samples.

How the data were processed

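RNA of single cells was measured in 4 libraries of neutrophils from mice infected with *Streptococcus pneumoniae*, 2 from BAL fluid and 2 from blood, collected at 24 h. Per the labels' protocols, red cells were lysed, neutrophils were enriched by magnetic beads that remove other cells, and libraries were made with droplet chemistry that reads the 3' end of transcripts, aiming at 5000 cells, and sequenced on a NextSeq instrument. The values used were raw UMI counts per gene and cell barcode, as deposited in 1 table of the whole series with 17410 gene rows and 12790 barcodes. Per the submitters' processing notes, Cell Ranger 3.1.0 and the genome build mm10 were used, with no role given for either. No barcode had fewer than 501 UMIs, and whether the submitters filtered barcodes is not given in the sources used here. Groups and library numbers were taken from the labels, and each barcode's library from its name. Every row named a gene, and 11 symbols had 2 rows. Of the symbols, 16761 were found in GENCODE M21 (genome build GRCm38), 16748 of them as a single gene, and coordinates are from that annotation. Genes whose symbols differ there are given no position. Counts are per gene, so that exons, introns and untranslated regions were not distinguished.

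Cells with at least 200 genes and at most 15% mitochondrial UMIs were kept, which left 12701 barcodes and removed 10 of BAL 1, 11 of BAL 4, 51 of blood 1 and 17 of blood 4. Scrublet, as in scanpy 1.11.5, marked 4 doublets, under 0.5% of cells, and is taken not to have worked, so doublets remain among the cells. The 12697 cells used were scaled to 10000 counts, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered with the Leiden method at a resolution of 1 on 15 neighbours (igraph 0.11.9, random seed 1). A cluster was named after the class with the largest share of its markers detected, from fixed markers of 13 classes, when at least 3 markers were each seen in 20% of its cells and its 10 leading genes did not go against the name. Neutrophil-like cells numbered 2259 in BAL 1, 3907 in BAL 4, 3036 in blood 1 and 2180 in blood 4. They were clustered again by themselves at a resolution of 0.5.

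Counts were summed over the neutrophil-like cells of each library, because cells are not replicates. The sums were compared with edgeR 4.0.16 (R 4.3.3), with TMM normalization (factors 0.968, 0.854, 1.09 and 1.11 for BAL 1, BAL 4, blood 1 and blood 4), filtering of low counts by group, a quasi-likelihood fit with the group as its only term and Benjamini-Hochberg adjustment at 0.05. The log2 difference is BAL minus blood with its standard error, and the mean CPM of each group is given with its SD over n = 2 libraries. A gene without a UMI in a group was given a lower bound from 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% counting interval. Intervals and floors cover counting error only.

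Genes were grouped in 32 lists with 662 members, of which 652 were found under the listed symbol, 4 under a synonym and 6 not found. The lists were primary, secondary and tertiary granules, calgranulins and stefins, chemokine ligands, cytokines, chemoattractant receptors, adhesion molecules, NF-kB pathway feedback, interferon-stimulated genes, hypoxia response, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, NADPH oxidase, pattern recognition receptors, and Fc and complement receptors. Further lists were immediate early genes, heat shock, unfolded protein and integrated stress response, oxidative stress and iron handling, survival genes, pro-apoptotic genes, inflammasome and pyroptosis, lysosome and cathepsins, eicosanoid synthesis, immunoregulatory molecules, antigen presentation by class I and by class II, cell cycle, actin cytoskeleton, and transcription factors. Lists with at least 5 tested members were tested with camera of limma 3.58.1, with its preset correlation of 0.01 and with an estimated correlation, and with fry, on log2 CPM with a prior count of 2.

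Named genes were the 10 with the largest log2 difference in each direction among genes past the threshold with a mean log2 CPM of at least 6 and no overlap between groups. Unnamed gene models (Gm and Rik symbols), mitochondrial and ribosomal protein genes and markers of other cell classes were left out of this ranking. From each list up to 3 members past the threshold with the largest absolute difference and a mean log2 CPM of at least 4 were added, and 21 genes were named in any case. The design, the lists, the markers, this rule and the first set of alternatives were fixed before the data were examined. A few named genes are not reported here.

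The test was tried on simulated counts drawn from the means and sizes of the neutrophil-like sums. With 2-fold changes it recovered 127 of 197 changed genes (64.5%) with 7 false calls among 9060 genes, and with 4-fold changes 196 of 199 (98.5%) with 14 false calls among 9087 genes. Few genes were changed, drawn evenly up and down, whereas 6692 of 9312 genes were called in the data. Normalization and false calls with that many changed genes were therefore not examined. Camera with its preset correlation recovered 10 of 10 lists of 20 members changed by 1.5-fold and called 0 of 20 unchanged lists. Genes were simulated independently and put into lists at random. False calls on lists with correlated members were therefore not examined, and the correlation was estimated at 0.707 for NF-kB pathway feedback. Counts of the libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 25.8 for BAL and 15.3 for blood, which does not show that they come from separate mice.

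Shares of cells of each class are given with exact binomial intervals, and groups were compared with an exact two-sided permutation test, whose smallest p is 0.3333 with 2 against 2. As an alternative for shares only, each cell was given the class with the most markers detected, at least 3 and more than for any other class. For shares of cells with a UMI and for list totals, each neutrophil-like cell was thinned to 2000 UMIs, and shallower cells were left out. The planned comparison of genes in other cell classes was not made, since none had 30 cells in each library.

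Alternatives were a replicate block, leaving out each library, DESeq2 1.42.0 and its size factors, library size alone, S100a8, S100a9, mitochondrial and ribosomal protein genes left out, no count filter, at least 50 counts in 2 libraries, all cells, and a per-cell rule with UMIs of at least 3 neutrophil markers and at most 1 marker of another class. Further ones were doublets kept, a stricter cell filter of 500 UMIs, 300 genes and 10% mitochondrial UMIs, thinned cells in equal numbers, a robust fit, a test against a log2 difference of 1, genes with a mean log2 CPM of at least 4, other clustering resolutions, and other depths of thinning. Leaving out cells above the 90th percentile of UMIs, barcodes with over 10% haemoglobin UMIs, the Cxcr4-led cluster or the Ngp-led cluster was added after seeing the data. For RNA from monocyte or macrophage-like cells, transcripts with at least 500 CPM in that class in both BAL libraries and under 10 CPM in both blood neutrophil sums, chemokine and cytokine genes left out, were compared with the share needed, with limits from 1000 bootstrap draws of the cells of the class. Tables were handled with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and anndata 0.12.19 in Python 3.11.15, and drawn with matplotlib 3.10.9.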

Results

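Neutrophils were enriched from bronchoalveolar lavage (BAL) fluid, the saline washed out of the airspaces of the lung, and from peripheral blood of male C57BL/6J mice aged 8 weeks. Both were collected 24 h after 1000000 colony-forming units of serotype 3 *Streptococcus pneumoniae*, a bacterium that causes pneumonia, had been placed in the left lung lobe. RNA of single cells was counted by unique molecular identifiers (UMIs) in 4 droplet libraries, 2 from BAL and 2 from blood, with the numbers 1 and 4 in each group. The 4 libraries held 12790 cell barcodes. BAL 1 held 2386 barcodes and 12251376 UMIs, BAL 4 held 4287 and 22188026, blood 1 held 3636 and 19357446, and blood 4 held 2481 and 12925513. The median barcode carried 3971, 3583, 4348 and 4662 UMIs in the same order. The labels do not say that libraries of a group came from separate mice, so the p-values below measure the spread between these libraries. No uninfected mouse was analysed here, and the design compares only airspace with blood in infected animals.

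Most cells in every library were neutrophil-like. Their share was 95.2% of the cells used in BAL 1, 91.4% in BAL 4, 84.7% in blood 1 and 88.5% in blood 4, with means of 93.3% ± 2.71 (SD, n = 2) in BAL and 86.6% ± 2.70 (SD, n = 2) in blood, an order that turned with a rule applied to each cell (83.6% and 87.5%). Of the 12 neutrophil markers, 4 were detected in BAL cluster 1, 7 in cluster 0 and 9 in clusters 5 and 7. All 12 were detected in BAL clusters 2 and 4 and in blood clusters 9, 10, 11 and 12. A stricter rule per cell, with at least 3 neutrophil markers and at most 1 of another class, kept 1215 and 2403 cells in BAL 1 and BAL 4. It kept 2295 and 1661 in blood 1 and blood 4, against 2259, 3907, 3036 and 2180 named by cluster. Alveolar macrophage-like cells, resident phagocytes of the airspace, made up 19 cells (0.801%, 95% exact binomial interval 0.483 to 1.25%) of BAL 1 and 263 cells (6.15%, 5.45 to 6.91%) of BAL 4. None was seen among 3585 cells of blood 1 and 2463 cells of blood 4, where 3 cells would be a share of 0.0837% and 0.122%. Epithelial cell-like barcodes numbered 66 in BAL 1, 40 in BAL 4, 0 in blood 1 and 1 in blood 4. Monocyte or macrophage-like cells made up 1.31% ± 0.191 (SD, n = 2) of BAL and 4.34% ± 3.56 (SD, n = 2) of blood. The class joined a cluster of BAL cells alone (cluster 3) and a cluster of blood cells alone (cluster 14). Its share of blood was 9.34% at a clustering resolution of 0.5 and 6.99% with the rule applied to each cell, which gave 0.793% of BAL. B cell-like cells (16 and 16) and platelet or megakaryocyte-like barcodes (24 and 33) were seen only in blood 1 and blood 4. A cluster left unnamed, led by Cd74 and class II genes, held 163 and 134 blood cells and 1 cell of each BAL library, and a cluster with markers of natural killer and T cells held 100 and 54 blood cells and 0 and 3 BAL cells. The exact permutation test, two-sided, gave p = 0.3333 for each class, the smallest value that 2 against 2 libraries allow. Red cell lysis and magnetic bead removal of other cells came before capture, so these are shares of the enriched suspension. No class other than the neutrophil had 30 cells in each of the 4 libraries, and genes were not compared between groups in any other class.

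The first comparison addressed how neutrophils of the infected airspace differed from those still in the blood. Airspace neutrophils carried far higher levels of several chemokine transcripts than blood neutrophils. Ccl3, a chemokine that draws phagocytes (chromosome 11, 83647844 to 83649355), stood at 12540.3 ± 1577 CPM (SD, n = 2; UMIs per 1000000, scaled by the trimmed mean of M-values, TMM) in BAL and 2.83 ± 0.966 in blood. Its log2 difference of 12.13 ± 0.35 (SE) was the largest among genes with a mean log2 CPM of at least 6 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.27e-09). Next came Cxcl3, a ligand of the neutrophil receptor Cxcr2 (9.66 ± 0.26, chromosome 5, 90786103 to 90789600), and Ccrl2, a receptor that binds chemerin without signalling (9.63 ± 0.35, chromosome 9, 111054486 to 111057519). Cxcl10, an interferon-induced chemokine, followed at 9.59 ± 0.71 (chromosome 5, 92346638 to 92348889), but moved to 8.75 without blood replicate 1 and 11.36 without blood replicate 4. The survival gene Bcl2a1b was higher by 9.27 ± 0.24, the chemokine Ccl4 by 8.92 ± 0.57 (8.28 without blood replicate 1 and 9.95 without blood replicate 4), the mitochondrial superoxide dismutase Sod2 by 8.26 ± 0.28, the cytokine Tnf by 7.85 ± 0.33, Cd274, which encodes the checkpoint ligand PD-L1, by 7.49 ± 0.20, and the matrix glycoprotein gene Thbs1 by 7.08 ± 0.29.

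Granule genes were among those with the largest deficits in BAL. Ngp, which encodes a protein of secondary granules (chromosome 9, 110419747 to 110423012), had a log2 difference of -3.71 ± 0.20, from 1110 ± 220 CPM (SD, n = 2) in blood to 84.8 ± 15.3 in BAL. Mmp8, neutrophil collagenase (chromosome 9, 7558456 to 7568485), was 11.2-fold higher in blood, at 4201 ± 647 against 375 ± 40.3 CPM (SD, n = 2; edgeR's quasi-likelihood test, adjusted p = 1.20e-07). Among genes with a mean log2 CPM of at least 6, Fam101b had the lowest value, -4.39 ± 0.17, followed by Cd244, an immune receptor of the SLAM family, at -3.84 ± 0.18. R3hdm4 (-3.34 ± 0.16), Ccpg1 (-3.31 ± 0.17), the lamin B receptor gene Lbr (-3.27 ± 0.17), the glucose transporter gene Slc2a3 (-3.26 ± 0.18), the calponin gene Cnn2 (-3.26 ± 0.17) and Hacd4, a gene of very long-chain fatty acid synthesis (-3.21 ± 0.15), completed the 10.

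Across the transcriptome, 9312 genes were tested on counts summed over the neutrophil-like cells of each library. Of these, 3301 were higher in BAL, 3391 were lower and 2620 did not pass an adjusted p of 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Differences of at least 2-fold were seen for 2502 of the higher and 2355 of the lower genes, and of at least 8-fold for 933 and 279. BAL and blood values did not overlap in 8069 genes (86.7%), where chance gives 33.3% for 2 against 2. Among the higher genes, 129 had no UMI in blood and 171 had 1 to 3, and 6 of the lower genes had none in BAL. The sums held 11178944 UMIs in BAL 1, 17551376 in BAL 4, 13214516 in blood 1 and 10265111 in blood 4. In the whole libraries S100a8 and S100a9 together took 6.35% and 5.99% of UMIs in BAL against 20.4% and 22.4% in blood, and scaling by library size alone moved the median gene by -0.28 on the log2 scale. The neutrophil-like cells lay in clusters 0, 1, 2, 4, 5 and 7 in BAL and in clusters 9, 10, 11 and 12 in blood, with few cells in those of the other group. Traces of other cells differed too. Epithelial markers summed to 139 and 92.8 CPM in the BAL neutrophil sums and to 0.605 and 0.292 in blood, and erythroid markers to 0.358 and 1.08 CPM in BAL and 736 and 2292 in blood.

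**Figure D1:**
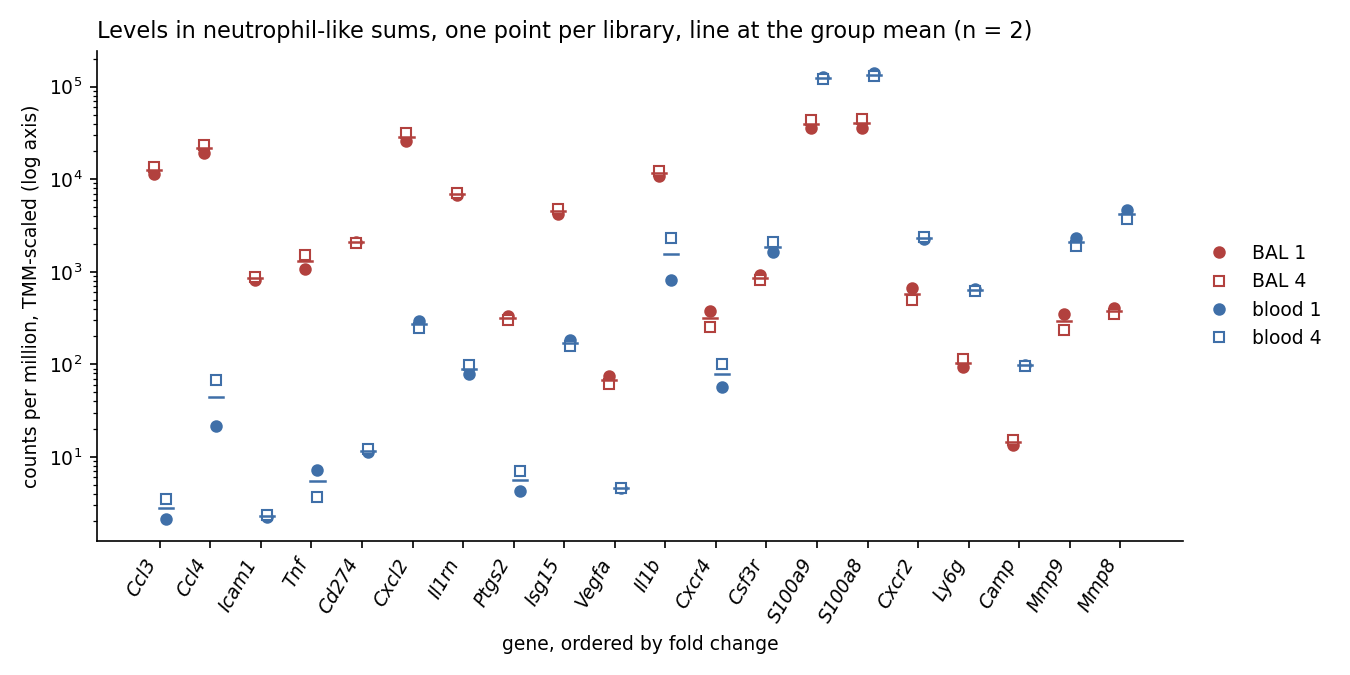
Levels of genes named in advance in neutrophil-like sums, in TMM-scaled CPM on a log axis, with a point for each library and a line at each group mean (n = 2). Ccl3 stood at a mean of 12540.3 in BAL and 2.83 in blood, while Mmp8 stood at 375 in BAL and 4201 in blood.

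Genes of marrow retention, chemokine sensing and growth factor sensing moved in different directions. Cxcr2, the receptor for neutrophil-attracting CXC chemokines (chromosome 1, 74153989 to 74161246), was lower in BAL by a log2 difference of -2.01 ± 0.18, at 580 ± 117 against 2326 ± 72.5 CPM (SD, n = 2). Cxcr4, the receptor that holds neutrophils in the marrow, was higher by 2.0 ± 0.26 (316 ± 88.3 against 79.2 ± 30.6 CPM, SD, n = 2). The receptor for granulocyte colony-stimulating factor, Csf3r, was lower (-1.12 ± 0.18), as was the neutrophil surface marker Ly6g (-2.62 ± 0.16). Of 14 chemoattractant receptors tested, 6 were higher, 4 lower and 4 not past the test. Besides Ccrl2, the higher ones included Gpr84, a receptor for medium-chain fatty acids (4.84 ± 0.19), and Ptafr, the receptor for platelet-activating factor (3.65 ± 0.17). The lower ones were Cxcr2, Ltb4r1, a leukotriene B4 receptor (-1.31 ± 0.15), C5ar2 (-1.22 ± 0.22) and Ccr2 (-2.84 ± 0.81). Ccr2 is also one of the monocyte markers, which summed to 285 and 192 CPM in the BAL neutrophil sums and 505 and 395 in blood. Whether traces of monocytes set the Ccr2 difference was not tested. The formyl peptide receptor genes Fpr1 (0.33 ± 0.15) and Fpr2 (0.03 ± 0.16) were among those that did not pass. The list did not pass (camera, adjusted p = 0.0738, and adjusted p = 0.319 with an estimated correlation). It did pass with a replicate block and in some other settings, with camera's adjusted p from 0.0274 to 0.109 over the alternatives with the preset correlation. Cxcr2, Csf3r, Ly6g, Mmp8, Mmp9, S100a8 and S100a9 are among the markers used to name the neutrophil clusters.

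Adhesion molecules were split. Of 22 tested, 9 were higher, 11 lower and 2 not past the test, with a median log2 difference of -0.42, a mean of 0.38 and an upward camera direction that did not pass (adjusted p = 0.488, and adjusted p = 0.558 with an estimated correlation). Icam1, a ligand of beta-2 integrins, was the highest (8.53 ± 0.21), at 848 ± 56.2 CPM in BAL and 2.30 ± 0.109 in blood (SD, n = 2). The integrin beta-1 gene Itgb1 was higher by 4.18 ± 0.16 and Itgb2l, a relative of the beta-2 integrin gene, was lower (-3.23 ± 0.30). Counts adjusted over the list alone equalled those adjusted over all genes, for this list and for each other list except 4 named below. Members that make up a small count and do not come from the naming rule, such as Ltb4r1 and Ccr2, were named after their values were seen, here and in the lists that follow.

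Granule genes were mostly lower in airspace neutrophils. In the secondary granule list 10 of 15 members were lower, 3 higher and 2 not past the test, with a median log2 difference of -1.67 (camera, adjusted p = 0.00292, and adjusted p = 0.380 with an estimated correlation). Besides Ngp, the antimicrobial peptide gene Camp (-2.75 ± 0.14) and Ifitm6 (-2.54 ± 0.22) were lower, while Cybb, the catalytic subunit of the phagocyte oxidase (1.72 ± 0.19), Orm1 (1.26 ± 0.19) and the siderophore-binding protein gene Lcn2 (1.01 ± 0.22) were higher. Without a cluster of blood cells led by Ngp, the list's call ended (limma's camera, adjusted p = 0.132) with a median of -1.24 (quartiles -1.81 and 1.35, against -2.50 and 0.39 with it), as it did without the cells of highest UMI count (adjusted p = 0.0567, median -1.34), and Camp turned to 0.26 without the Ngp-led cluster. In the tertiary granule list 8 of 11 were lower, 1 higher and 2 not past the test, with a median of -2.56 (camera, adjusted p = 1.35e-04, and adjusted p = 0.319 with an estimated correlation). Mmp9, the gelatinase of these granules, was lower (-2.87 ± 0.22), as was Padi4, the enzyme that citrullinates histones (-2.88 ± 0.15), and the metal transporter gene Slc11a1 was higher (1.90 ± 0.15). Of 4 primary granule members tested, 3 were lower and 1 higher, too few for a set test. Serpinb1a, an inhibitor of granule proteases, was lower (-4.20 ± 0.34), with the serine protease gene Prtn3 (-3.31 ± 0.40) and the maturation factor gene Cebpe (-0.60 ± 0.22), and Srgn, the granule proteoglycan serglycin, was higher (2.20 ± 0.21).

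Of the calgranulins and stefins, 9 of 12 were lower, 2 higher and 1 not past the test, with a median of -1.45 (camera, adjusted p = 0.0379, and adjusted p = 0.535 with an estimated correlation). S100a8 and S100a9, which form the calcium-binding protein calprotectin, were lower by log2 differences of -1.75 ± 0.29 and -1.66 ± 0.28, and S100a6 by -1.85 ± 0.20. The stefin BC100530 was lower (-2.03 ± 0.17), though its reads and those of the other stefins may be split among near-identical copies. Cstb, an inhibitor of cathepsins, was higher (5.59 ± 0.22), as was S100a10 (1.21 ± 0.30). The list's call also ended without BAL replicate 1 (limma's camera, adjusted p = 0.101), with a per-cell marker rule (0.0902), with S100a8, S100a9, mitochondrial and ribosomal protein genes left out (0.128) and without the highest-UMI cells (0.0543), the Cxcr4-led cluster (0.0622) or the Ngp-led cluster (0.0508).

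Most chemokine and cytokine transcripts tested were higher in the airspace. Of 13 chemokine ligands 11 were higher and 2 lower, with a median log2 difference of 8.91, or 8.32 with members unseen in blood set to their lower bound (camera, adjusted p = 2.51e-10, and adjusted p = 0.319 with an estimated correlation). Cxcl2, a ligand of Cxcr2, stood at 28485 ± 3920 CPM in BAL and 270 ± 33.9 in blood (SD, n = 2; 6.72 ± 0.28, edgeR's quasi-likelihood test, adjusted p = 1.80e-08). The 2 lower members were Pf4, a platelet chemokine (-4.01 ± 0.60), and Ccl6 (-0.56 ± 0.20). Pf4 was scarce, at 0.537 and 0.171 plain CPM in the BAL sums and 3.71 and 9.35 in blood. Platelet markers, Pf4 among them, summed to 2.77 and 2.39 CPM in BAL and 8.70 and 18.8 in blood. Whether traces of platelets set the Pf4 difference was not tested. Of 19 cytokines 17 were higher and 2 lower, with a median of 4.13 (camera, adjusted p = 1.89e-11, and adjusted p = 0.319 with an estimated correlation). Il1a, an alarmin, had 56990 UMIs in BAL and 0 in blood, which makes it at least 18996-fold higher with 3 counts taken over the blood group. Il1rn, the antagonist of interleukin-1, was higher by 6.28 ± 0.23 and Il1b by 2.90 ± 0.40. Il1b differed between the blood libraries, at 1557 ± 1050 CPM (SD, n = 2) against 11606 ± 1067 in BAL, and its log2 difference was 2.31 without blood replicate 1 and 3.81 without blood replicate 4. The lower members were the tumour necrosis factor family genes Tnfsf13b (-1.97 ± 0.16) and Tnfsf14 (-0.86 ± 0.18). Monocyte markers summed to 285 and 192 CPM in the BAL neutrophil sums and 505 and 395 in blood. Alveolar macrophage markers summed to 993 and 366 in BAL and 622 and 259 in blood, where no alveolar macrophage-like cell was seen. One of them, Chil3, is also on the secondary granule list. In the BAL sums Lpl stood at 0.805 and 1.54 plain CPM, Ear2 at 0.805 and 1.42, Mrc1 at 0.447 and 1.42 and Marco at 0.179 and 1.25. The macrophage marker sums therefore do not measure traces of macrophages alone.

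All 23 members of the list of NF-kB pathway feedback genes were higher in BAL, with a median of 4.14 (camera, adjusted p = 1.08e-23, and adjusted p = 0.319 with an estimated correlation). Besides Bcl2a1b they included Traf1, an adaptor of tumour necrosis factor receptors (8.76 ± 0.23), and Tnfaip3, which encodes the NF-kB inhibitor A20 (8.65 ± 0.21). Of 40 interferon-stimulated genes 39 were higher, with a median of 3.48 (camera, adjusted p = 5.59e-25, and adjusted p = 0.319 with an estimated correlation). The guanylate-binding protein gene Gbp5 was higher by 6.69 ± 0.23, the antiviral enzyme gene Rsad2 by 6.06 ± 0.23 and the ubiquitin-like modifier gene Isg15 by 4.72 ± 0.20. Slfn1 was the member that did not pass (0.13 ± 0.19). Among 26 immediate early genes 20 were higher, 21 when adjusted over the list alone, and 3 lower, with a median of 1.90 (camera, adjusted p = 1.05e-09, and adjusted p = 0.319 with an estimated correlation). The stress-induced transcription factor genes Maff (8.29 ± 0.22), Atf3 (7.97 ± 0.32) and Egr1 (5.85 ± 0.18) were higher, with Atf3 at 7.26 without blood replicate 1 and 8.97 without blood replicate 4, while Fos (-0.94 ± 0.32), Jund (-0.73 ± 0.18) and Klf2 (-0.38 ± 0.15) were lower. Of 33 transcription factors of neutrophil state 19 were higher, 10 lower and 4 not past the test, with a median of 0.91 (camera, adjusted p = 0.00150, and adjusted p = 0.380 with an estimated correlation). The highest members were Maff, Atf3 and the basic helix-loop-helix repressor gene Bhlhe40 (6.67 ± 0.21).

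Most stress and survival genes were higher in BAL. In the list of oxidative stress and iron handling 19 of 21 members were higher and 2 lower, with a median of 3.84 (camera, adjusted p = 9.08e-11, and adjusted p = 0.319 with an estimated correlation). The peroxiredoxin gene Prdx1 was higher by 6.56 ± 0.26, the cystine transporter gene Slc7a11 by 5.29 ± 0.30 and the thioredoxin reductase gene Txnrd1 by 4.79 ± 0.21. The iron exporter gene Slc40a1 (-0.77 ± 0.20) and the glutathione reductase gene Gsr (-0.98 ± 0.15) were lower. Of 18 genes of the unfolded protein and integrated stress responses 12 were higher, 2 lower and 4 not past the test, with a median of 2.31 (camera, adjusted p = 3.09e-04, and adjusted p = 0.319 with an estimated correlation). Ppp1r15a, which restores translation after stress, was higher by 6.03 ± 0.34 (5.44 without blood replicate 1 and 6.82 without blood replicate 4), the amino acid transporter subunit Slc3a2 by 5.09 ± 0.21 and the endoplasmic reticulum chaperone gene Dnajb9 by 3.02 ± 0.16. Of 11 heat shock genes 9 were higher and 2 not past the test, with a median of 1.91 (camera, adjusted p = 0.00862, and adjusted p = 0.319 with an estimated correlation). Hspa1a, which shares near-identical sequence with Hspa1b, was higher by 3.91 ± 0.27, Hsp90aa1 by 2.14 ± 0.15 and Dnaja1 by 0.79 ± 0.13. The heat shock call ended when all cells of each library were summed (limma's camera, adjusted p = 0.269).

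Of 14 survival genes 13 were higher, with a median of 2.44 (camera, adjusted p = 2.39e-11, and adjusted p = 0.319 with an estimated correlation). Bcl2a1d (10.00 ± 0.26), Bcl2a1b and Bcl2a1a (8.79 ± 0.23), copies of an anti-apoptotic gene, were the highest, and reads may be split among them because their sequences are near-identical. Mcl1, another anti-apoptotic gene of neutrophils, did not pass (0.31 ± 0.17). Of 16 pro-apoptotic genes 9 were higher, 3 lower and 4 not past the test, with a median of 0.79 (camera, adjusted p = 0.00659, and adjusted p = 0.319 with an estimated correlation). The higher ones included Bax (5.64 ± 0.19), Pmaip1 (4.20 ± 0.17) and Bcl2l11 (4.11 ± 0.21), all of the mitochondrial pathway of apoptosis. The lower ones included Bad (-1.77 ± 0.17) and Tnfrsf10b (-1.26 ± 0.42). Of 15 inflammasome and pyroptosis genes 9 were higher, 2 lower and 4 not past the test, with a median of 1.52, and the list did not pass (camera, adjusted p = 0.0619, and adjusted p = 0.319 with an estimated correlation). With a replicate block and in some other settings it passed, camera's adjusted p running from 0.0139 to 0.162 over the alternatives with the preset correlation. The sensor gene Nlrp3 was higher (3.97 ± 0.23), while Dfna5, which encodes the pore-forming gasdermin E, was lower (-3.64 ± 0.18), as was Nek7, a partner of Nlrp3 (-2.19 ± 0.22).

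Of 61 nuclear genes of oxidative phosphorylation 42 were lower, 4 higher and 15 not past the test, with a median of -0.64 (camera, adjusted p = 1.98e-04, and adjusted p = 0.406 with an estimated correlation). The complex I subunit genes Ndufb11 (-2.64 ± 0.14), Ndufb10 (-2.25 ± 0.15) and Ndufb7 (-1.56 ± 0.14) were lower, and Ndufa12 (1.5 ± 0.18), Ndufs3 (0.69 ± 0.22), Cox7a2 (0.57 ± 0.15) and Atp5b (0.38 ± 0.13) were higher. Of 13 mitochondrially encoded genes 3 were lower, or 2 adjusted over the list alone, 1 was higher and 9 did not pass (camera, adjusted p = 0.541, and adjusted p = 0.783 with an estimated correlation). The lower ones were mt-Nd6 (-1.47 ± 0.42), mt-Co1 (-0.68 ± 0.18) and mt-Co2 (-0.53 ± 0.19), and mt-Nd2 was higher (0.44 ± 0.13) but lower, at -0.43, when all cells were summed. Leaving out BAL replicate 1 ended the calls of mt-Co1 and mt-Co2, leaving out blood replicate 4 that of mt-Co2, and leaving out BAL replicate 4 or blood replicate 1 that of mt-Nd2. Median mitochondrial shares per barcode were 0.254% and 0.327% in BAL and 0.560% and 0.656% in blood. Of 16 glycolysis genes 7 were higher and 6 lower, with a median of -0.03 that turned to 0.05 with DESeq2 size factors (camera, adjusted p = 0.541, and adjusted p = 0.808 with an estimated correlation). Hexokinase 2 (Hk2) was higher (2.25 ± 0.20), while the isomerase gene Gpi1 (-2.87 ± 0.15) and Slc2a3 were lower. Of 18 hypoxia response genes 9 were higher and 4 lower, with a median of 0.82 (camera, adjusted p = 0.0303, and adjusted p = 0.431 with an estimated correlation), and the call ended with a stricter count filter (adjusted p = 0.0596). Bhlhe40, the angiogenic factor gene Vegfa (3.89 ± 0.18) and the oxidoreductase gene Ero1l (2.95 ± 0.22) were higher, and Pfkfb4 (-2.79 ± 0.14), Mxi1 (-1.93 ± 0.18), Egln1 (-1.06 ± 0.25) and Bnip3l (-0.45 ± 0.13) were lower.

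Subunits of the NADPH oxidase, which makes superoxide, went both ways, with 4 of 8 higher and 2 lower (camera, adjusted p = 0.541, and adjusted p = 0.795 with an estimated correlation). Cybb, the proton channel gene Hvcn1 (4.93 ± 0.35), Ncf1 (1.00 ± 0.19) and Cyba (0.79 ± 0.17) were higher, and the lower ones included Rac2 (-1.01 ± 0.15). Of 12 genes of eicosanoid synthesis 4 were higher, 5 lower and 3 not past the test, with a median of 0.11 that turned to -0.18 when scaled by library size alone (camera, adjusted p = 0.541, and adjusted p = 0.655 with an estimated correlation). The prostaglandin enzymes Ptgs2 (5.84 ± 0.22), Ptges (5.48 ± 0.25) and Ptges3 (1.79 ± 0.15) were higher, as was Hpgds, whose blood count of 1 to 3 UMIs gave a BAL over blood ratio of 660 (counting interval 118 to 26107). The leukotriene enzymes Alox5 (-2.71 ± 0.20), Alox5ap (-2.37 ± 0.17) and Lta4h (-2.07 ± 0.20) were lower, with Ptgs1 (-1.45 ± 0.35) and the thromboxane synthase gene Tbxas1 (-1.94 ± 0.21).

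Sensing, degradation and surface regulation genes were mostly higher in BAL. Of 23 pattern recognition receptors and partners 18 were higher, 2 lower and 3 not past the test, with a median of 2.38 (camera, adjusted p = 2.07e-07, and adjusted p = 0.319 with an estimated correlation). The C-type lectin gene Clec4n (5.95 ± 0.22), the kinase gene Irak2 (5.29 ± 0.16) and the endotoxin co-receptor gene Cd14 (4.30 ± 0.24) were higher, and Tlr1 (-1.03 ± 0.22) and Trem3 (-0.46 ± 0.13) were lower. Of 13 Fc and complement receptors and related genes 9 were higher, 2 lower and 2 not past the test, with a median of 1.31 (camera, adjusted p = 0.0130, and adjusted p = 0.319 with an estimated correlation). The inhibitory receptor gene Fcgr2b (4.19 ± 0.17) and complement C3 (2.56 ± 0.14) were higher, and the paired immunoglobulin-like receptor genes Pirb (-2.19 ± 0.15) and Pira2 (-0.63 ± 0.13) were lower. Of 23 lysosome and cathepsin genes 19 were higher and 1 lower, or 2 lower when adjusted over the list alone, with a median of 2.30 (camera, adjusted p = 3.07e-08, and adjusted p = 0.319 with an estimated correlation). The galactosidase gene Gla (6.70 ± 0.27) and the cathepsin gene Ctsz (5.14 ± 0.19) were higher, and the protease-activating cathepsin gene Ctsc was lower (-0.91 ± 0.18). Of 18 immunoregulatory surface molecules and enzymes 13 were higher, 2 lower and 3 not past the test, with a median of 1.69 (camera, adjusted p = 1.61e-06, and adjusted p = 0.319 with an estimated correlation). Besides Cd274 they included Irg1, the enzyme that makes itaconate (5.51 ± 0.25), and the transglutaminase gene Tgm2 (5.06 ± 0.16), while Siglece (-0.43 ± 0.15) and Il4ra (-0.51 ± 0.14) were lower.

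Of 19 genes of class I antigen presentation 18 were higher and Pdia3 did not pass (-0.06 ± 0.14), with a median of 2.93 (camera, adjusted p = 3.29e-11, and adjusted p = 0.319 with an estimated correlation). H2-Q4 was higher by 4.45 ± 0.22, the class I transactivator gene Nlrc5 by 4.17 ± 0.19 and the chaperone calnexin gene Canx by 3.51 ± 0.15. Of 5 class II genes tested 4 were higher, with a median of 2.50 (camera, adjusted p = 0.0213, and adjusted p = 0.319 with an estimated correlation). The invariant chain gene Cd74 (4.33 ± 0.18), H2-Eb1 (2.66 ± 0.42), the cathepsin gene Ctss (2.50 ± 0.16) and H2-Aa (1.28 ± 0.34) were higher. When all cells were summed, the class II list was lower in BAL (limma's camera, adjusted p = 8.56e-04) and Cd74 stood at -1.88. Of 34 actin cytoskeleton genes 23 were lower and 6 higher, or 8 higher when adjusted over the list alone, with a median of -0.64 (camera, adjusted p = 0.0110, and adjusted p = 0.558 with an estimated correlation), and the call ended when all cells were summed (adjusted p = 0.0963). Limd2 (-2.61 ± 0.21), the actin-severing gelsolin gene Gsn (-2.36 ± 0.15) and Arhgdib (-1.96 ± 0.19) were lower. Of 6 cell cycle genes tested 3 were higher and 3 lower (camera, adjusted p = 0.701, and adjusted p = 0.783 with an estimated correlation). The chromatin protein gene Hmgb2 (-2.51 ± 0.15), the centromere histone gene Cenpa (-0.91 ± 0.17) and Tubb5 (-0.72 ± 0.22) were lower. Pcna (2.01 ± 0.25), Stmn1 (1.39 ± 0.40) and Mki67 were higher, the last with 1170 UMIs in BAL and 3 in blood, a ratio of 390 (counting interval 133 to 1894).

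**Figure D2:**
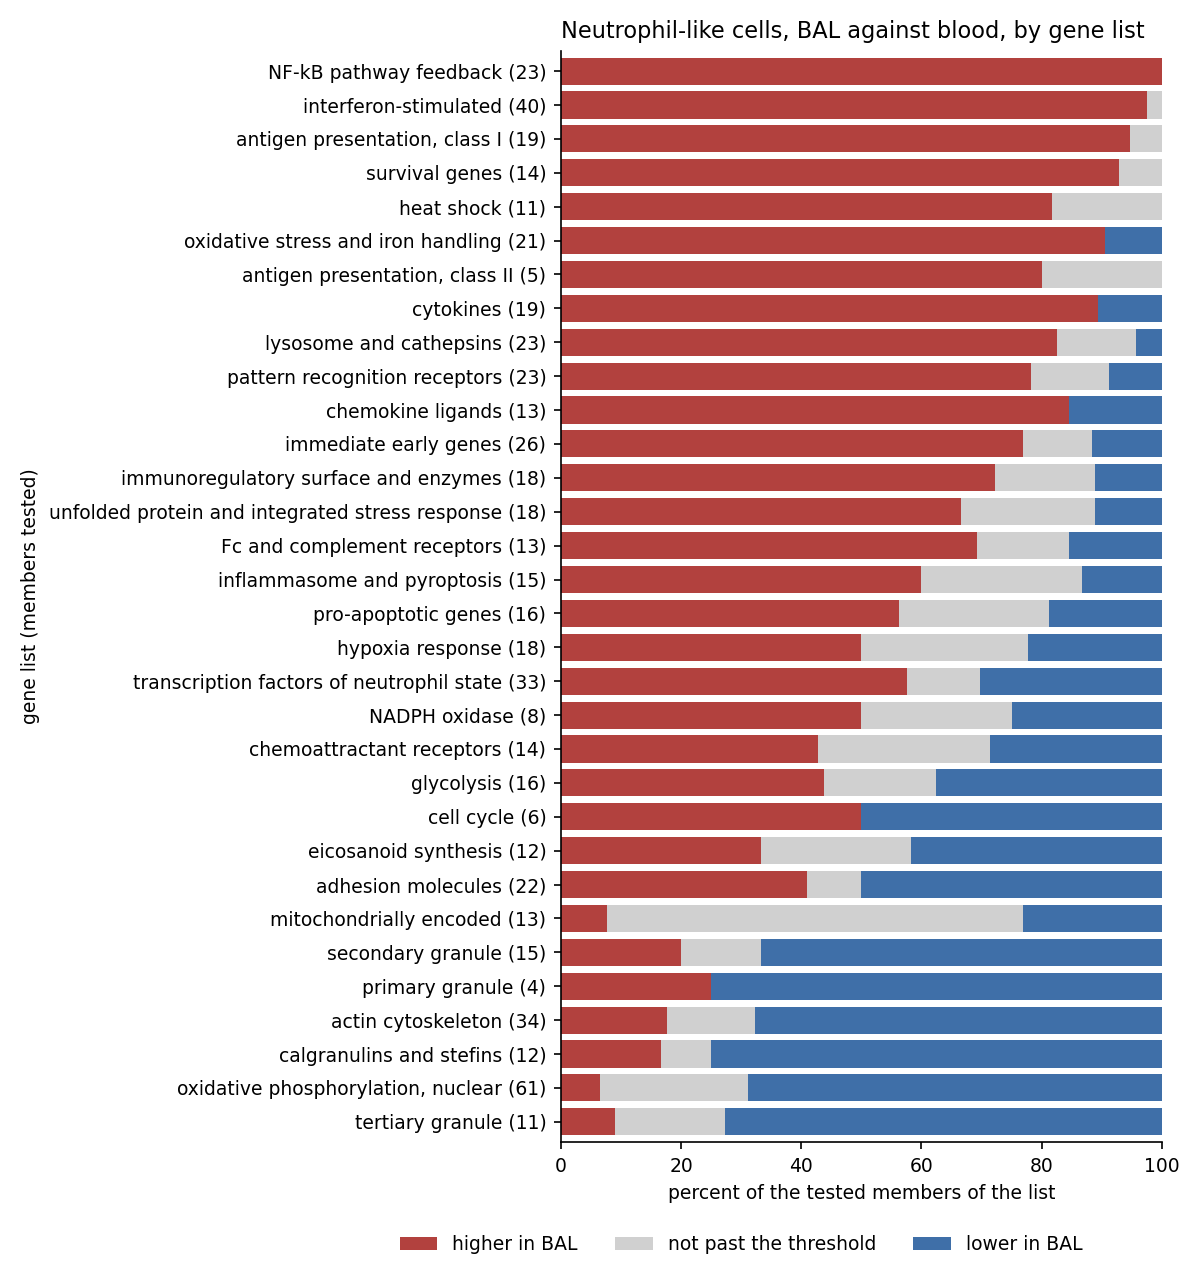
Share of the tested members of each gene list, in percent on the horizontal axis, that were higher, not past the threshold or lower in BAL neutrophil-like sums, with the number tested in parentheses and lists ordered by the difference between both shares. All 23 NF-kB feedback genes were higher, and 8 of 11 tertiary granule genes were lower.

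Of the 31 lists with at least 5 tested members, 23 passed with the preset correlation of camera, 18 toward higher and 5 toward lower values, and 0 passed with an estimated correlation. With 4 libraries the estimate rests on few residual degrees of freedom. For pro-apoptotic genes (-0.0311) and unfolded protein and integrated stress genes (-0.0248) it lay below the preset 0.01. Their unadjusted camera p still rose, from 0.00361 to 0.0891 and from 1.39e-04 to 0.0541. The lost calls therefore do not measure correlation between genes alone. The directional test of fry, which does not compare a list with other genes, called 28. Only 2 libraries per group stand behind these calls. The spread between replicates was small, a median absolute log2 difference of 0.152 between the BAL libraries and 0.126 between the blood libraries, against 0.907 between the group means. How far the list calls depend on this spread was not tested. The calls of Csf3r, S100a8, S100a9, Cybb, Hspa1a, Dnaja1 and Ctss ended when all cells of each library were summed.

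The share of cells with a UMI of a gene depends on its level and on the UMIs read per cell, and 0 UMIs do not show that a cell lacks the transcript. With each neutrophil-like cell thinned to 2000 UMIs, Ccl3 was seen in 92.2% ± 2.31 (SD, n = 2) of BAL cells and 0.553% ± 0.185 of blood cells. Cxcl2 was seen in 96.8% ± 1.49 and 27.0% ± 4.48, Cd274 in 82.8% ± 4.51 and 2.75% ± 0.258, and Tnf in 56.5% ± 6.62 and 1.06% ± 0.535. Isg15 was seen in 83.5% ± 0.994 and 23.3% ± 0.358, and Ptgs2 in 22.6% ± 2.30 and 1.00% ± 0.520. Mmp8 was seen in 16.3% ± 3.12 of BAL cells and 90.2% ± 5.74 of blood cells, Cxcr2 in 37.6% ± 9.28 and 98.5% ± 0.676, and Ly6g in 8.49% ± 0.714 and 56.3% ± 5.44. Il1b was seen in 54.1% of cells of blood 1 and 82.3% of blood 4, against 90.8% and 86.2% in BAL 1 and BAL 4, and unthinned in 66.5% and 89.1% against 92.7% and 87.7%. Of the 21 genes, 12 had a higher mean share in BAL, and the exact permutation test, two-sided, gave its smallest p of 0.3333 for Ccl3 and Mmp8. Unthinned shares were 93.5% and 0.910% for Ccl3, 96.9% and 38.9% for Cxcl2, 87.3% and 4.65% for Cd274, 68.0% and 2.58% for Tnf, 83.8% and 35.8% for Isg15, and 31.7% and 1.72% for Ptgs2. They were 21.2% and 90.5% for Mmp8, 46.1% and 99.6% for Cxcr2, and 13.5% and 70.01% for Ly6g. Thinning left out 231 cells of BAL 1, 395 of BAL 4, 191 of blood 1 and 133 of blood 4.

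UMIs of these genes were also counted in other cell types, in which free RNA and the cells' own expression were not separated. Among the 66 epithelial cell-like barcodes of BAL 1 (median 1435 UMIs) and the 40 of BAL 4 (median 1247), Ccl3 was seen in 13.6% and 20%, Cxcl2 in 36.4% and 27.5%, Isg15 in 21.2% and 15%, Tnf in 4.55% and 5% and Cd274 in 3.03% and 5%. Cxcr2, Mmp8 and Ly6g were seen in none of them, which the exact binomial interval bounds at 5.44% and 8.81%. The neutrophil-like cells had medians of 3977 and 3436 UMIs in these libraries and 4048 and 4489 in blood 1 and blood 4. Among the 16 B cell-like cells of each blood library (medians 5033 and 4744.5 UMIs), Ccl3 and Cxcl2 were seen in none, Mmp8 in 0% and 6.25%, Cxcr2 in 0% and 18.8%, Isg15 in 12.5% and 37.5% and Il1b in 6.25% and 25%.

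**Figure D3:**
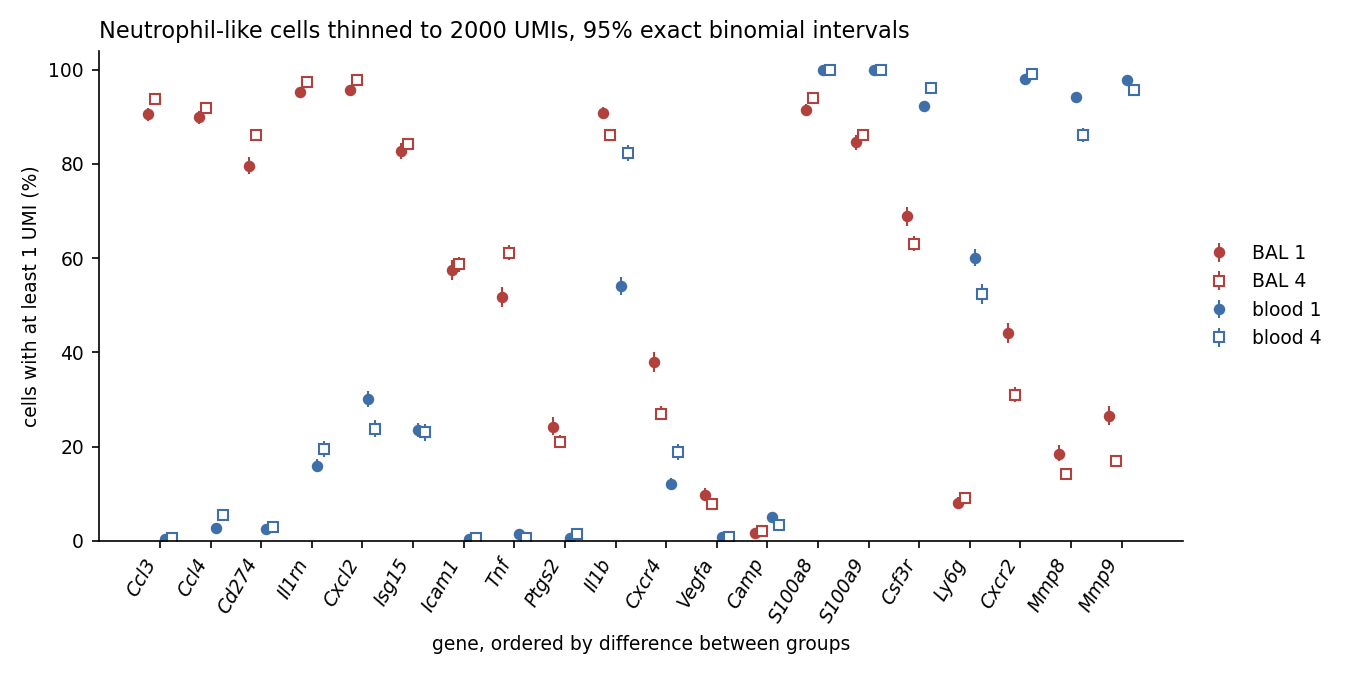
Percent of neutrophil-like cells with at least 1 UMI of genes named in advance, after thinning each cell to 2000 UMIs, with a point for each library and 95% exact binomial intervals. Ccl3 was seen in 92.2% of BAL cells and 0.553% of blood cells on average, and Mmp8 in 16.3% and 90.2%.

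Relative to their mean, calgranulin and stefin totals varied more between the neutrophils of a BAL library than between those of a blood library, while their SD over cells was similar. At 2000 UMIs per cell, calgranulins and stefins took a mean of 124 UMIs in BAL 1 and 136 in BAL 4, and of 594 and 553 in blood 1 and blood 4. The 10th and 90th percentiles were 11 and 369 in BAL 1, 15 and 366 in BAL 4, 422 and 760 in blood 1, and 349 and 733 in blood 4. Their SD over cells was 148 and 146 UMIs in BAL against 141 and 157 in blood, the SD relative to the mean 1.195 and 1.08 in BAL against 0.237 and 0.284 in blood, and their variance-to-mean ratio 177 and 157 against 33.3 and 44.6. Interferon-stimulated genes took means of 88.5 and 82.2 UMIs in BAL, against 14.9 and 14.1 in blood, with 10th and 90th percentiles of 8 and 198 in BAL 1 and 5 and 27 in blood 1. Their variance-to-mean ratios were 67.0 and 56.6 against 9.44 and 8.60, but with the higher mean the SD relative to the mean was similar, at 0.870 and 0.830 in BAL and 0.797 and 0.781 in blood. Chemokine ligands took 127 and 130 UMIs in BAL and 4.30 and 4.56 in blood, and genes of oxidative stress and iron handling 232 and 308 against 29.4 and 33.4. No test was made across cells, which are not replicates.

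**Figure D4:**
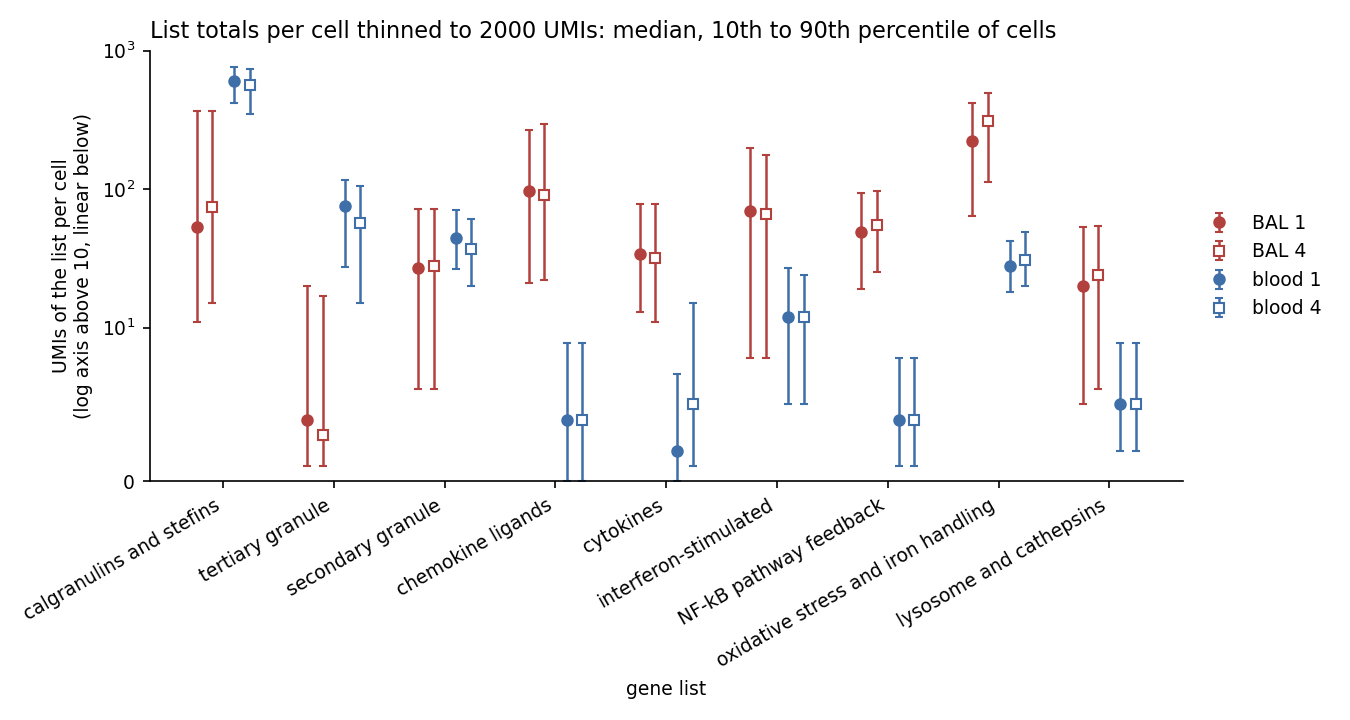
UMIs of 9 gene lists per neutrophil-like cell thinned to 2000 UMIs, on an axis that is logarithmic above 10 and linear below, with the median and the 10th to 90th percentile of cells for each library. Calgranulins and stefins ran from 11 to 369 UMIs in BAL 1, and interferon-stimulated genes from 8 to 198.

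Neutrophil-like cells of BAL and blood shared almost no cluster. Clustered by themselves they fell into 7 clusters, 4 made mostly of BAL cells and 3 mostly of blood cells. The BAL clusters held 99.4% of the neutrophil-like cells of BAL 1 and 99.8% of those of BAL 4, and the blood clusters held 99.9% and 100% of those of blood 1 and blood 4.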

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

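The tests below on RNA from other cells, on depth, on library size, on the Ngp-led cluster by list and on cycling cells were chosen only after the results they bear on had been seen, and that on Ptpre before. Barcodes that failed the cell filter enter no comparison, and among them 38 in blood 1 and 14 in blood 4 had over 10% of their UMIs from haemoglobin genes, against 0 in BAL 1 and 0 in BAL 4, above the limit that a count of 0 allows.

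The first pattern was the rise of chemokines and cytokines in BAL neutrophil-like sums (28 members higher), for which RNA of alveolar macrophages would need, for each member in both BAL libraries, at least 93.7 times the share that Lpl, Ear2, Mrc1 and Marco allowed (0.034% in BAL 1 and 0.102% in BAL 4), with the lowest ratio at Ccl9. RNA of monocyte or macrophage-like cells would need at least 3.42 times the share allowed by Apoe (2.11% and 1.84%), the most permissive of Apoe, Fn1 and C1qb, for 25 members, with the lowest ratio at Cxcl16, and for Ccl5 more than 2 times the share allowed by 6 of 22 transcripts abundant in those cells and scarce in blood neutrophils (lower 95% bootstrap limits, both BAL libraries), a test set up after that on Apoe, by which Ccl5 needed 1.70 times the share, had left it open. For Ccl2 and Il6 only 1 of these transcripts, Ms4a4c, allowed that little, and neutrophil RNA and RNA from those cells cannot be told apart, because Fn1 (0.0167% and 0.347%) falls short in both libraries but for Ccl2 in BAL 4 its bootstrap limits include the share needed, and Il6 rests on 19 and 16 UMIs. A difference in depth per cell is argued against by 96.2% of tested members (25 of 26, all but Tnfsf9) passing the test with equal UMIs per cell and equal cells per library. For the 26 members other than Ccl2 and Il6, expression by the airspace neutrophils themselves may account for the rise, as a hypothesis found and tested on the same data.

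The second pattern was the lower level of secondary and tertiary granule genes in BAL, with 18 of 26 members lower and a median log2 difference of -1.84. The Ngp-led cluster left out held 684 cells of blood 1 and 257 of blood 4. These cells as the whole cause are argued against for tertiary granules. The tertiary median went from -2.56 to -2.22 (quartiles -2.67 and -0.85) with 8 of 11 members still lower without them. For secondary granules the median went from -1.67 (quartiles -2.50 and 0.39) to -1.24 (-1.81 and 1.35), and 8 of 15 members were lower. Ltf turned to 2.28 and Camp to 0.26, and the list's call ended (limma's camera, adjusted p = 0.132). For this list such cells and a difference in other neutrophils cannot be told apart, because the members go both ways. Neutrophil-like cells clustered by themselves gave a larger Ngp-led cluster, with 53.9% of those of blood 1 and 39.7% of those of blood 4. That cluster was not left out, so that immature blood cells in a wider sense were not tested. For a few abundant genes taking most of the counts, the test set could not decide. With library size alone the members' median lay at -1.80 relative to that of all genes. This is more than 1 below it but also within the interquartile range of all genes (2.16), so that the value met both outcomes set. A single factor per library cannot alter this difference either. With S100a8, S100a9, mitochondrial and ribosomal protein genes left out, the median was -1.66 for secondary granules (10 of 15 lower). It was -2.54 for tertiary granules (8 of 11 lower), and DESeq2 size factors gave -1.60 and -2.49. S100a8 and S100a9 took a larger share of UMIs in blood than in BAL. Genes abundant in BAL were not left out, such as Fth1, at 62570 and 81880 plain CPM in the BAL neutrophil sums and 5664 and 6678 in blood. A size factor moves all genes of a library alike. These medians therefore do not settle whether a few abundant genes are the whole cause. A loss of granule transcripts on entry to the airspace, and a different age of the cells in each place, were not tested and stay open.

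The third pattern was Mki67, a proliferation marker, with 1170 UMIs in BAL neutrophil-like cells and 3 in blood, a gene outside the naming rule chosen after its values were seen. It was found in 162 cells (7.17%) of BAL 1 and 252 cells (6.45%) of BAL 4. Cycling cells in the class, or RNA from cycling alveolar macrophages, are argued against by Top2a, with 4 UMIs there against 438 beside 472 of Mki67 in alveolar macrophage-like cells, since the ratio of Top2a to Mki67 was at most 0.00664 times that in these macrophages. Reads running on from the neighbouring gene Ptpre are argued against by the ratio of Mki67 to Ptpre being 500.2 times higher in BAL, with 4359 UMIs of Ptpre in BAL and 5591 in blood. Ptpre lies on the plus strand and Mki67 on the minus strand. Such reads would add to Mki67 only if counting ignored the strand, and the ratio bears on that case alone. An overlapping gene on the other strand or a transcript of this locus that is not in the annotation was not tested, so that the source of these UMIs stays open.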

How the results depend on the processing

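The settings that left out highest-UMI cells, haemoglobin-rich barcodes, the Cxcr4-led cluster or the Ngp-led cluster were chosen only after seeing the data. Of the values of 106 named genes under 23 settings, 2404 kept direction and side of the threshold, 26 lost significance and 3 reversed, and for 31 lists under 21 settings 592 did, 34 lost significance, 20 gained it and 1 reversed. Reversed values were Camp at 0.26 with the Ngp-led cluster left out and, with all cells summed, mt-Nd2 at -0.43, Cd74 at -1.88 and the class II list (limma's camera, adjusted p = 8.556e-04, range over alternatives 8.556e-04 to 0.0349). The cause was not tested, though the sums of all cells include blood cells led by Cd74 and class II genes. edgeR called 6692 genes (3301 higher and 3391 lower), and 3745 (2027 and 1718) against a log2 difference of 1 and 2965 (1503 and 1462) with a mean log2 CPM of at least 4, where fewer genes are tested. Library size alone gave 2738 higher and 3971 lower, and DESeq2's Wald test 3080 and 2669. All cells gave 2454 and 2327, with 47 called in the opposite direction. Leaving out each library in turn gave 6001 to 6419 genes (3076 to 3350 higher and 2925 to 3135 lower) and 23 to 25 lists (18 to 20 higher and 4 to 5 lower), with the lone library assumed to vary like the others. Leaving out a blood library moved the folds of Cxcl10, Ccl4, Atf3, Ppp1r15a and Il1b by over 1.5 times with no change of call (Cxcl10 8.75 and 11.36). Without BAL replicate 1 the calls of mt-Co1 (-0.44) and mt-Co2 (-0.23) ended, without blood replicate 4 that of mt-Co2 (-0.44), without BAL replicate 4 that of mt-Nd2 (0.35) and without blood replicate 1 that of mt-Nd2 (0.37).

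With an estimated correlation camera called 0 lists (0 higher and 0 lower), against 23 with the preset one, and fry called 28. Lower lists fell from 5 to 3 with highest-UMI cells left out and to 3 with the Ngp-led cluster left out, and the cause was not tested. Over the camera alternatives with the preset correlation the adjusted p ran from 1.04e-04 to 0.132 for secondary granules, 0.00743 to 0.128 for calgranulins and stefins, 0.00375 to 0.0596 for hypoxia, 0.00111 to 0.269 for heat shock and 0.00105 to 0.0963 for actin. Lists not called passed in some settings, with ranges of 0.0274 to 0.109 for chemoattractant receptors, 0.0139 to 0.162 for inflammasome and 8.944e-04 to 0.966 for cell cycle. Among leave-one-out settings, chemoattractant receptors passed without blood replicate 1 (0.0360) or 4 (0.0476), and inflammasome without BAL replicate 1 (0.0403), blood replicate 1 (0.035) or blood replicate 4 (0.0208).

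The libraries share only a number: deviations of same-numbered libraries correlated at 0.00233 over 9312 genes and 0.0167 over 3798. With the replicate block, 6690 genes (3308 higher and 3382 lower) and 25 lists (20 higher and 5 lower) were called, and chemoattractant receptors (adjusted p = 0.0449) and inflammasome (adjusted p = 0.0185) passed in limma's camera.

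With the rule that gave each cell the class with the most markers, the mean neutrophil-like share of BAL was 83.6% against 93.3%. That of blood was 87.5% against 86.6%, so that BAL turned from the higher share to the lower. The monocyte or macrophage-like share of BAL was 0.793% with the same rule and 1.10% with the stricter cell filter against 1.31%. That of blood was 9.34% at a resolution of 0.5 and 6.99% with the same rule against 4.34%. Neutrophil-like cells made 11 clusters at a resolution of 1 and 5 at 0.3, against 7. The causes were not tested. In the simulation 64.5% of 2-fold changes were recovered, and recovery was not examined by depth.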

Other observations

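Only the hypothesis on list totals was set down before its values were seen, and the genes described first were chosen after their values were seen. In plain CPM of class sums, Ccl3 stood at 11060 in neutrophil-like cells of BAL 1 and 11657 in BAL 4, against 1769 and 3355 in monocyte or macrophage-like and 233 and 303 in alveolar macrophage-like cells. Cxcl2 stood at 24892 and 26682 in neutrophils against 6105 and 5299.8 in monocyte or macrophage-like cells and 192 and 697 in alveolar macrophages, and Il1b at 10504 and 10551 against 2487 and 4330, and 46.6 and 376. Levels in neutrophils and monocyte or macrophage-like cells were closer for Tnf, at 1031 and 1299 against 711 and 872, and for Isg15, at 4125 and 4059 against 4215 and 6058. The monocyte chemokine genes Ccl2 and Ccl7 were higher in monocyte or macrophage-like cells, at 2601 and 1786 for Ccl2 against 9.12 and 8.26 in neutrophils, and at 749 and 1222 for Ccl7 against 0.358 and 0.228. The acute phase gene Saa3 stood at 9870 and 11864 in monocyte or macrophage-like cells and 494 and 873 in neutrophils. Il18, which encodes a cytokine processed by inflammasomes, stood at 433 and 399 in alveolar macrophages and 43.6 and 51.2 in neutrophils. The monocyte or macrophage-like class rested on 28 and 62 cells and the alveolar macrophage-like class on 19 and 263, with no test between classes.

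The blood libraries differed in Il1b, at 889 CPM in blood 1 and 2549 in blood 4 of the neutrophil-like sums. Scgb1a1, a secretory product of airway club cells, was seen in 22.7% and 9.29% of BAL neutrophil-like cells and in none of blood, where exact intervals allow up to 0.121% and 0.169%. Haemoglobin Hbb-bs was seen in 3.66% and 3.03% of blood neutrophil-like cells and in 0.044% and 0.102% of BAL cells. Heat shock genes took few UMIs per thinned cell in BAL, a mean of 1.93 and 1.72 against 1.17 and 1.14 in blood, but their variance-to-mean ratio was 82.4 and 45.8 against 1.11 and 1.13. The median of 1 UMI and the 90th percentile of 3 UMIs were the same in all 4 libraries, so that the ratio in BAL was set by few cells.

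Within BAL, lists rose and fell together or apart over thinned cells, each list taken as a share of the cell's UMIs outside the other list. Spearman's correlation over cells of BAL 1 and BAL 4 was 0.293 and 0.366 between interferon-stimulated genes and chemokine ligands, leaving out Cxcl10, which is in both lists (0.463 and 0.515 with it), against 0.218 and 0.151 in blood. It was -0.470 and -0.476 in BAL between calgranulins and lysosome genes, against -0.0824 and -0.06 in blood. Calgranulins were related to interferon-stimulated genes at 0.2998 and 0.369 in BAL and at -0.137 and -0.0694 in blood. Cells are not replicates, and no p is given. A hypothesis was that interferon-stimulated and oxidative stress genes are led by different cells of the airspace, which would give a correlation under -0.2 in both BAL libraries. It was -0.134 in BAL 1 and -0.350 in BAL 4, so that the hypothesis was met in BAL 4 alone and stays undecided.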
